A study of Danio rerio with 6 samples.

How the data were processed

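The study compared zebrafish embryos mutant for mycn with wild-type embryos of the AB strain at 72 h after fertilization. Per the labels there were 6 samples, namely 2 wild-type and 2 mutant Ribo-seq samples and 1 RNA-seq sample of each genotype. Per the labels' protocols, embryos for Ribo-seq were dissociated and lysed, the lysate was digested with RNase and ribosomes were isolated on a sucrose gradient, while RNA-seq libraries followed a standard Illumina preparation. The labels do not say whether the replicates came from separate clutches or pools, so p-values measure the spread between these samples, which may be technical.

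The deposited values are ratios, the translation efficiency of each of 21392 genes in each of the 4 Ribo-seq libraries. Per the file headers each column belongs to 1 Ribo-seq library and derives from FPKM values, so the authors divided the FPKM of a library's footprints by an FPKM of mRNA; which RNA-seq sample was the denominator, and any filter or offset, is not given in the sources used here. Per the submitters' processing notes STAR, featureCounts and limma were used with the genome build GRCz11, without versions or roles. Gene symbols were used as the file gives them. Footprint counts, mRNA counts and FPKM values were not analysed here, so the depth is unknown and no counting interval can be given for a ratio.

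The precision of the ratios was judged from the values. A value that another gene of the same library shares to 9 significant digits marks a ratio of small whole numbers, and 64.7% to 67.1% of the values above 0 in a library were of this kind. The Pearson correlation of log2 values across the 17601 tested genes, which are not independent replicates, was 0.823 between the wild-type libraries, 0.811 between the mutant libraries, and 0.732 to 0.755 across genotypes. Over the 2626 tested genes with no repeated value it was 0.984, 0.983 and 0.960 to 0.966. A gene listed at 0 in any library was left out of the main test; 3791 genes were.

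The design was written before the data were examined and assumed counts, with a model of both assays. Because the file holds ratios, the test written for that case was used: limma (version 3.58.1, in R 4.3.3) on log2(value + 0.1), with an empirical Bayes trend, mutant against wild type, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 0.1) scale, which understates the change of genes with low ratios. Each gene had 2 residual degrees of freedom. Comparisons of footprints alone and of mRNA alone, and the model with an interaction of assay and genotype, were planned and not run. Groups of 2 samples are too small for an outlier test or for other splits of the samples.

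Gene lists were fixed before the data were examined. The 33 lists cover 17 pathways (large-subunit, small-subunit and mitochondrial ribosomal proteins, ribosome biogenesis factors, RNA polymerase I and III subunits, translation factors, aminoacyl-tRNA synthetases, nucleotide synthesis, amino acid synthesis and ATF4 response, mTOR pathway, cell cycle, unfolded protein response, sterol synthesis, oxidative phosphorylation, proteasome, chaperones, and 1 list that is not reported here) and 16 sets of cell type markers (enterocytes, intestinal secretory cells, exocrine pancreas, hepatocytes, endocrine pancreas, skeletal and cardiac muscle, lens, photoreceptors, neurons, neural progenitors, erythroid cells, leukocytes, epidermis, cartilage and fibrous connective tissue). They were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Alternatives were fry and camera with an estimated correlation, which rests on the 2 residual degrees of freedom and so has little power here. Lists with fewer than 5 tested members were given no test.

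The rule for named genes, written beforehand, took mycn, myca and mycb, then the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups, a mean of at least 10 and an assigned symbol, or failing those the genes with the smallest p, and up to 4 members per list. A mean of at least 10 was meant for abundances and keeps only extreme ratios. After the unit was known, the rule was therefore extended to genes without repeated values past the threshold when fitted alone, with no minimum mean, and to the 4 members of each list with the smallest p, also with no minimum. Members given beyond these were chosen after their values were seen.

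The steps were tested on simulated data before use. The simulated noise was drawn independently for each library, without an mRNA error shared by both libraries of a genotype. For the gene test, 100 genes were changed by a log2 fold of 1 and 100 by 2. For the list test, 100 lists of 30 genes shifted by a log2 fold of 0.4 were drawn; all 100 had an unadjusted p under 0.05, as did 3 of 100 unshifted lists. Alternatives were quantile normalization, median centring, a fit without trend, no filter, a minimum of 5 in at least 2 libraries, pseudocounts of 0.01 and 1, a replicate block, a minimum change of 2-fold, and each library left out in turn. A robust fit and the set without repeated values, there also with camera at an estimated correlation, were added after the data were seen. A RefSeq gene table of assembly GRCz12tu, which is not the build of the file, was used only for gene names and neighbours, and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.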

Results

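Zebrafish embryos mutant for mycn, a member of the Myc family of transcription factors whose human counterpart is mutated in Feingold syndrome, were compared with wild-type embryos at 72 h after fertilization. Ribo-seq, which sequences the mRNA fragments that ribosomes protect from nuclease, was done on 2 samples of each genotype, and RNA-seq on 1 sample of each genotype. The values analysed here were translation efficiencies, the abundance of a gene's ribosome footprints relative to that of its mRNA, for 21392 genes in each of the 4 Ribo-seq libraries. The comparison asked which mRNAs carried more or fewer footprints per mRNA in the mutants, among them those of the ribosome, of its assembly and of the intestine, which the study's title names. The median translation efficiency was 0.746 and 0.734 in the wild-type libraries and 0.752 and 0.736 in the mutant libraries. FPKM values are scaled to the total of each library, so the ratios are relative to those of other genes. Similar medians therefore do not show that overall translation was unchanged, and a change shared by all genes could not be seen. Between 1254 genes (5.86%) and 2135 genes (9.98%) were listed at 0 in a library, and 17601 genes above 0 in all 4 libraries were tested. Footprint and mRNA abundances were not analysed here, so the depth behind a ratio is unknown, and a higher ratio can come from more footprints or from less mRNA.

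In mycn mutants, translation efficiency was higher for the markers of the exocrine pancreas, enterocytes and photoreceptors and for the enzymes and regulators of sterol synthesis, and lower for cartilage markers, cytosolic aminoacyl-tRNA synthetases and the mTOR pathway. These were 7 of 33 gene lists fixed before the data were examined, called with camera at a preset correlation between genes. None of the 7 list calls held when the correlation between genes was estimated from the data, with an adjusted p = 0.615 for each. With an estimate, camera uses the 2 residual degrees of freedom, which raises p by itself. The loss therefore does not show that correlation between genes produced the calls. The estimate was below the preset 0.01 for sterol synthesis (-0.0198), enterocytes (-0.0261) and photoreceptors (-0.0233), and above it for the other called lists. With fry, which asks only whether a list's members move one way on balance, 2 of the 7 passed, enterocyte and photoreceptor markers (adjusted p = 0.0288 for each). Like those of single genes, the p-values of fry appear to leave out the error of the mRNA measurement. Those of camera at the preset correlation do not allow for an mRNA error shared by a list's members beyond that correlation. The median change in these lists ran from 2.65-fold higher in the exocrine pancreas to 0.82-fold in cartilage. The ribosomal proteins and the ribosome biogenesis factors were not called. No single gene passed the test in the fit of all 17601 genes, whereas 36 of the 2626 genes with no repeated value did when fitted alone. With a pseudocount of 1 in place of 0.1 all 7 calls held with smaller medians, such as a log2 fold of 0.78 for the exocrine pancreas, 0.22 for sterol synthesis and -0.13 for cartilage.

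**Figure D1:**
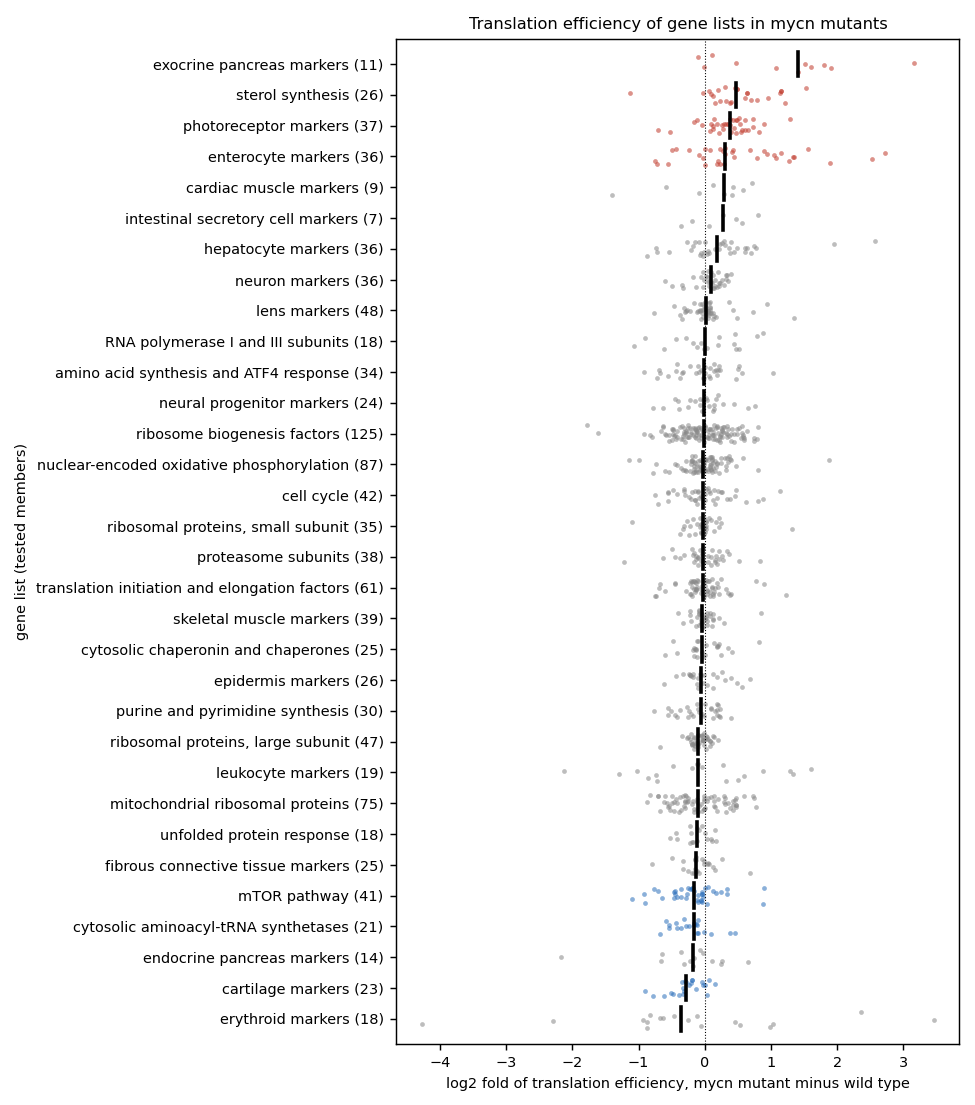
Log2 fold of translation efficiency (mycn mutant minus wild type, on the log2(value + 0.1) scale) of each tested member of the gene lists described here, with 1 point per gene and a black bar at the list's median. Lists called higher with camera at the preset correlation are red, those called lower blue, and the others grey; the numbers of tested members stand in parentheses, and the medians run from 1.41 in exocrine pancreas markers to -0.36 in erythroid markers.

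The digestive enzymes of the exocrine pancreas had the largest median among the lists. Of 11 tested members, 9 were higher in mutants and 2 lower, with a median log2 fold of 1.41 (camera adjusted p = 0.000394; adjusted p = 0.615 with an estimated correlation). No member passed over all genes tested, and 5 passed when adjusted over the list alone. The translation efficiency of cel.1, a lipase secreted with pancreatic juice, was 0.390 ± 0.00364 (SD, n = 2) in wild type and 1.40 ± 0.203 in mutants, a log2 fold of 1.604 (SE 0.204). That of prss59.1, a trypsin-like protease, was 0.366 ± 0.160 against 4.33 ± 2.58. The chymotrypsin-like ctrl was at 0.933 ± 0.0995 against 2.97 ± 1.24. Another 10 of the 21 listed members were at 0 in at least 1 library, and with these included the median was 0.48 (adjusted p = 0.0442).

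Of 36 enterocyte markers, 28 were higher and 8 lower, with a median log2 fold of 0.31 (camera adjusted p = 0.00327; adjusted p = 0.615 with an estimated correlation). Without mycn mutant replicate 2 the median was 0.487 over the same members, and 0.545 over the 41 members above 0 in the other libraries. When adjusted over the list alone, 1 member passed, and none did over all genes. It was tm4sf4, a membrane tetraspanin-like protein, at 1.06 ± 0.103 (SD, n = 2) in wild type and 4.20 ± 0.153 in mutants. The brush-border peptidase anpepb had a log2 fold of 1.15 (SE 0.246), whereas the apolipoprotein apoa4b.2 had one of -0.75 (SE 0.191). Neither the 7 intestinal secretory cell markers (median 0.27, adjusted p = 0.593) nor the 14 endocrine pancreas markers (median -0.17, adjusted p = 0.313) were called. The 36 hepatocyte markers had a median of 0.19 and were not called with camera (adjusted p = 0.217, or 0.615 with an estimated correlation). They passed with fry (adjusted p = 0.0288). Over the fits that left out 1 library, the medians ran from 0.128 to 0.415 for secretory cells (0.10 after quantile normalization), from -0.403 to -0.028 for the endocrine pancreas, and from 0.0952 to 0.220 for hepatocytes.

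Sterol synthesis was higher in 24 of 26 members, with a median log2 fold of 0.47 (camera adjusted p = 0.000394; adjusted p = 0.615 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. Cyp51, which demethylates lanosterol, was at 0.7501 ± 0.134 (SD, n = 2) in wild type and 1.55 ± 0.153 in mutants. Sc5d, a desaturase late in the pathway, was at 0.429 ± 0.224 against 1.36 ± 0.0502. Mevalonate kinase, encoded by mvk, went the other way, from 0.832 ± 0.0483 to 0.329 ± 0.0461, a log2 fold of -1.12 (SE 0.200).

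Photoreceptor markers were higher in 32 of 37 tested members, with a median log2 fold of 0.38 (camera adjusted p = 0.000802; adjusted p = 0.615 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. The ultraviolet cone opsin opn1sw1 was at 0.320 ± 0.00569 (SD, n = 2) in wild type and 0.595 ± 0.0247 in mutants. The blue cone opsin opn1sw2 was at 0.193 ± 0.00427 against 0.391 ± 0.0961, and the cone arrestin arr3a at 0.205 ± 0.00392 against 0.366 ± 0.0173. The list lost its call without mycn mutant replicate 2 (adjusted p = 0.0742), with a median of 0.413 in that fit. The 36 neuron markers had a median of 0.10 and were not called with camera (adjusted p = 0.628, or 0.627 with an estimated correlation). They passed with fry (adjusted p = 0.0288).

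Cartilage markers were lower in 20 of 23 members, with a median log2 fold of -0.29 (camera adjusted p = 0.00252; adjusted p = 0.615 with an estimated correlation). No member passed over all genes or when adjusted over the list alone. Col9a1b, a chain of cartilage collagen, was at 2.63 ± 0.148 (SD, n = 2) in wild type and 1.49 ± 0.207 in mutants. The proteoglycan acana was at 0.805 ± 0.0206 against 0.549 ± 0.0210, and the transcription factor sox9a at 0.808 ± 0.0140 against 0.625 ± 0.00482. The call was lost without wild-type replicate 1 (adjusted p = 0.0574, median -0.237) and without mycn mutant replicate 2 (adjusted p = 0.0742, median -0.239).

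Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower in 18 of 21 members, with a median log2 fold of -0.16 (camera adjusted p = 0.0232; adjusted p = 0.615 with an estimated correlation). The histidine enzyme hars was at 0.743 ± 0.0446 (SD, n = 2) in wild type and 0.425 ± 0.0144 in mutants, and the phenylalanine enzyme subunit farsa at 0.873 ± 0.0216 against 0.549 ± 0.0898. The mTOR pathway was lower in 32 of 41 members, with a median of -0.16 (camera adjusted p = 0.0306; adjusted p = 0.615 with an estimated correlation). Among its members, rragca, a Rag GTPase that recruits the mTOR complex to lysosomes, was at 1.49 ± 0.0306 against 0.647 ± 0.0506. The inhibitory components nprl2, nprl3 and tsc2 had log2 folds of -0.92, -0.77 and -0.90, so the members with the smallest p included both activators and inhibitors of the pathway. No member of either list passed over all genes or when adjusted over the list alone. The synthetase call was lost when any 1 of the 4 libraries was left out (adjusted p of 0.0583 without wild-type replicate 1, 0.208 without wild-type replicate 2, 0.0792 without mutant replicate 1 and 0.174 without mutant replicate 2), although the medians were -0.233, -0.169, -0.210 and -0.234 in these fits. The mTOR call was lost without wild-type replicate 1 (0.605), mutant replicate 1 (0.0676) or mutant replicate 2 (0.174), with medians of -0.064, -0.179 and -0.138 over the same members, and the median was -0.28 without wild-type replicate 2.

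**Figure D2:**
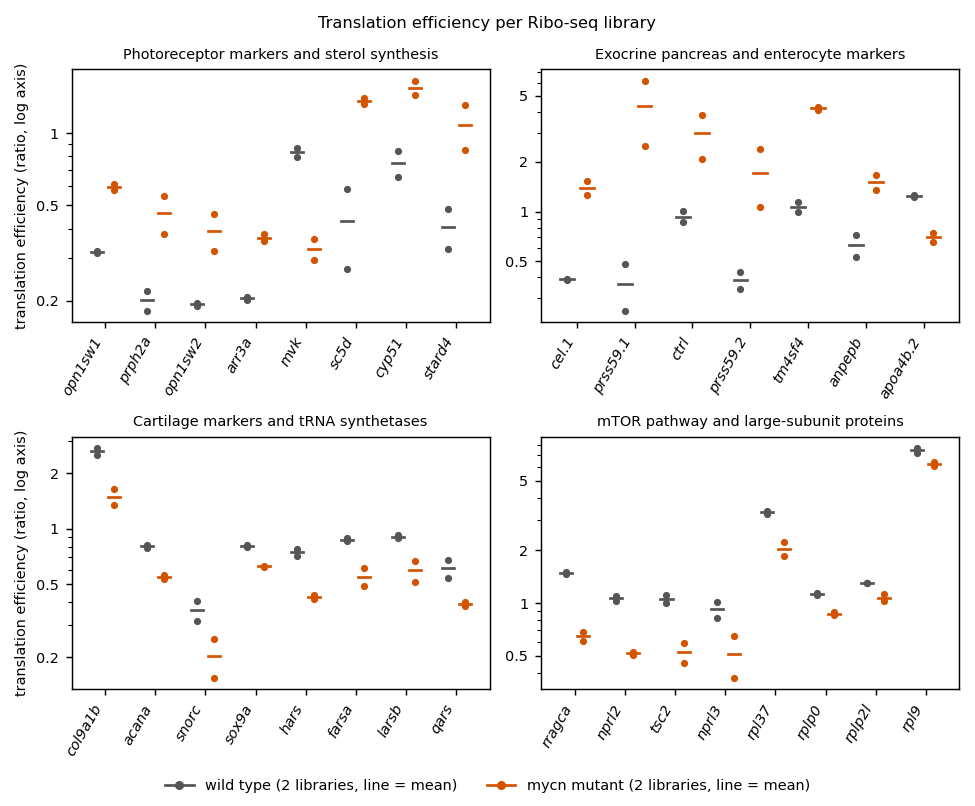
Translation efficiency (ratio, log axis) in each of the 4 Ribo-seq libraries of up to 4 members with the smallest p in each of the 7 called lists and in the large-subunit ribosomal proteins; points are libraries and lines are means of 2. Both mutant libraries of opn1sw1, cel.1 and tm4sf4 lie above both wild-type libraries, and those of acana, hars and rragca below. Members picked by a small p tend to show such separation, which 44.8% of all 17601 tested genes had (33.3% by chance).

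The lists of ribosomal proteins and of ribosome assembly were not called with camera. Large-subunit ribosomal proteins were lower in 34 of 47 members, but the median log2 fold was -0.095 and the list was not called (camera adjusted p = 0.188). It passed with fry (adjusted p = 0.0397) and with camera after quantile normalization (adjusted p = 0.0270), but not with camera at an estimated correlation (adjusted p = 0.615). The lowest p in the list was that of rpl37, at 3.30 ± 0.0634 (SD, n = 2) in wild type and 2.04 ± 0.271 in mutants (adjusted p = 0.399), and rplp0, a protein of the ribosomal stalk, was at 1.13 ± 0.0111 against 0.871 ± 0.0248. Small-subunit ribosomal proteins had a median of -0.026 over 35 members (adjusted p = 0.593), and mitochondrial ribosomal proteins one of -0.098 over 75 members (adjusted p = 0.313), which was 0.0090 without wild-type replicate 1. The 125 ribosome biogenesis factors had a median of -0.0088, with 59 higher and 66 lower (adjusted p = 0.648), and a median between 0.0022 (without mutant replicate 2) and -0.0695 (without wild-type replicate 2) when 1 library was left out, and of -0.0605 after quantile normalization. Among these, the nucleolar proteins ddx21 and nolc1 had log2 folds of 0.79 (SE 0.210) and 0.75 (SE 0.201), and rrp8 one of -1.78 (SE 0.461); none passed. The medians were 0.0078 for RNA polymerase I and III subunits (adjusted p = 0.843), a sign that turned after quantile normalization (-0.031), median centring (-0.018) and without wild-type replicate 2 (-0.0092), and -0.032 for translation initiation and elongation factors (adjusted p = 0.593). Over the fits that left out 1 library, the medians ran from -0.0021 (without mutant replicate 1) to -0.042 (without mutant replicate 2) for these factors, from -0.017 (without wild-type replicate 2) to -0.046 (without wild-type replicate 1) for the small subunit, down to -0.164 (without mutant replicate 1) for mitochondrial ribosomal proteins and up to 0.117 (without wild-type replicate 1) for the polymerases.

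The pathway lists named next were not called either. Median log2 folds were -0.062 for purine and pyrimidine synthesis (adjusted p = 0.313), -0.0076 for amino acid synthesis and the ATF4 response (0.648), and -0.11 for the unfolded protein response (0.313). They were -0.020 for nuclear-encoded oxidative phosphorylation (0.648), -0.027 for proteasome subunits (0.719), -0.036 for cytosolic chaperonin and chaperones (0.761), and -0.026 for the cell cycle (0.734), whose mean was 0.0033. Among markers of other tissues, the medians were -0.036 for skeletal muscle (adjusted p = 0.676), 0.29 for cardiac muscle (0.719), -0.0082 for neural progenitors (0.719), -0.097 for leukocytes (0.635), and -0.13 for fibrous connective tissue (0.313). Lens markers had a median of 0.020 and were ranked lower by camera (adjusted p = 0.843), and their median was -0.0055 after median centring. Epidermis markers had a median of -0.061 and a mean of 0.0018 (adjusted p = 0.843). Several of these medians changed sign when 1 library was left out. Without wild-type replicate 1 they were 0.021 for oxidative phosphorylation, 0.019 for the proteasome, 0.046 for chaperones, 0.035 for the cell cycle, 0.086 for neural progenitors and 0.0071 for epidermis. Without wild-type replicate 2 they were 0.037 for the proteasome, -0.026 for cardiac muscle and -0.022 for the lens. Without mutant replicate 1 they were 0.028 for oxidative phosphorylation, 0.048 for chaperones, 0.015 for the cell cycle, 0.070 for neural progenitors and -0.028 for the lens. Without mutant replicate 2 they were 0.029 for the proteasome, 0.14 for leukocytes and 0.0024 for amino acid synthesis and the ATF4 response, and cardiac muscle was at 0.082. Other medians kept their sign but moved, that of purine and pyrimidine synthesis from -0.0029 without mutant replicate 2 to -0.12 without wild-type replicate 2, and that of the unfolded protein response from -0.047 without mutant replicate 1 to -0.135 without wild-type replicate 2. Of the medians that turned, the opposite ends were 0.491 for cardiac muscle without wild-type replicate 1 (0.428 without mutant replicate 1), -0.185 for neural progenitors, -0.087 for chaperones and -0.052 for the cell cycle without wild-type replicate 2, -0.225 for leukocytes and -0.041 for amino acid synthesis and the ATF4 response without mutant replicate 1, and -0.054 for oxidative phosphorylation without mutant replicate 2.

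Erythroid markers differed in both directions and by larger amounts than the members of the other lists, with an SD of 1.67 over their log2 folds and a median of -0.36 (camera adjusted p = 0.313). Of 18 members, 6 were higher and 12 lower, and 4 globin genes passed when adjusted over the list alone, although none did over all genes. The beta-type globin hbbe1.1 was at 0.617 ± 0.0731 (SD, n = 2) in wild type and 7.77 ± 0.189 in mutants, and the alpha-type hbae1.1 at 15.0 ± 1.79 against 78.1 ± 16.9. In the other direction, hbbe3 was at 9.39 ± 3.93 against 0.371 ± 0.0522, and hbae3 at 1.48 ± 0.0868 against 0.723 ± 0.00622. The p of these 4 globin genes adjusted over the list alone, from limma, ran from 0.00113 for hbbe1.1 to 0.0318 for hbae3. The values of hbbe3 were repeated in all 4 libraries, which marks ratios of small whole numbers, whereas hbbe1.1 and hbae3 had no repeated value. Globin genes of each type lie beside similar copies of the same type, and how reads that match several copies were counted is not given in the sources used here.

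**Figure D3:**
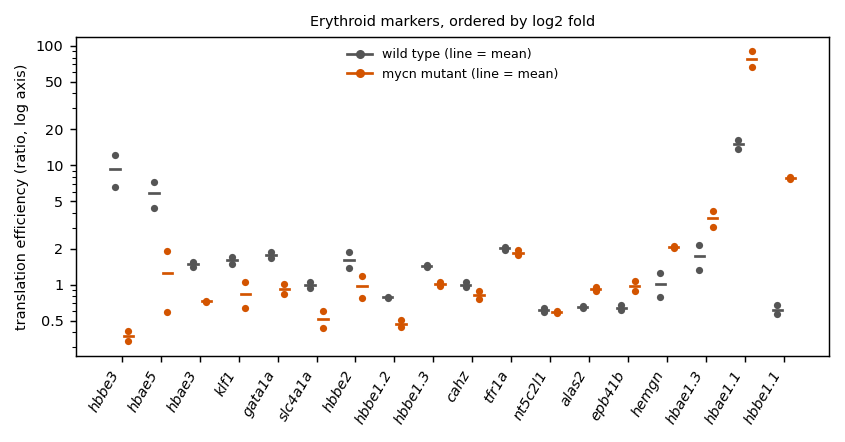
Translation efficiency (ratio, log axis) of the 18 erythroid markers in the 4 Ribo-seq libraries, ordered by log2 fold; points are libraries and lines are means of 2 libraries per genotype. Hbbe3 is lower and hbae1.1 and hbbe1.1 are higher in both mutant libraries.

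For mycn itself, translation efficiency was 0.446 and 0.302 in the wild-type libraries and 0.429 and 0.342 in the mutant libraries, a log2 fold of 0.045 (SE 0.265, limma adjusted p = 0.964). The paralogs myca and mycb had log2 folds of -0.58 (SE 0.552) and -0.14 (SE 0.201), and neither passed. A ratio of footprints to mRNA does not show how much mycn mRNA or protein was made, so it does not check the genotype labels.

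Among single genes, 0 of 17601 passed limma's test at an adjusted p of 0.05, with a smallest adjusted p of 0.101. At an unadjusted p under 0.05 there were 2023 (11.5%), of which 1194 were higher and 829 lower in mutants. On simulated ratios with the same spread, this fit recovered 0 of 100 genes changed by a log2 fold of 1 and 0 of 100 changed by 2, so a count of 0 does not show that no gene differed. Many ratios took a value that other genes of the same library share to 9 significant digits, as ratios of few reads do. Fitted alone, the 2626 genes with no such repeated value gave 36 calls, 19 higher and 17 lower, and 511 genes (19.5%) at an unadjusted p under 0.05. This set was chosen after the data were seen. An unrepeated ratio does not show that the mRNA was well covered, since many footprints over little mRNA can also give one. Most of the 36 had a mean ratio of at least 10 over the 4 libraries, as did only 235 of all 17601 tested genes. Examples were sars2 (mean 8923 in wild type, 16656 in mutants), FO744833.2 (1168 against 3939) and spata6l (515 against 1487). Others were ANKFN1 (43.0 against 105) and tlr1 (290 against 48.9). The calls also included low ratios, such as apoa2 (0.711 against 1.22). In this set simulated changes of a log2 fold of 1 and 2 were recovered for 86 and 93 of 100 genes, with 2 false calls. The simulated noise was independent between libraries and held no mRNA error shared by both libraries of a genotype. The false calls therefore do not measure how many of the 36 come from such error.

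Of the genes called in this set and carrying an assigned symbol, the largest rises were those of hbbe1.1 (log2 fold 3.46), spata6l (1.53), ANKFN1 (1.296), pkd1b (1.295), slc47a4 (1.203), sars2 (0.90), rnf213a (0.88) and slc12a5a (0.86). Pkd1b, related to the polycystins, was at 0.510 ± 0.0544 (SD, n = 2) in wild type and 1.39 ± 0.0554 in mutants (limma adjusted p = 0.0206). Slc12a5a, a neuronal potassium chloride cotransporter, was at 2.90 ± 0.206 against 5.35 ± 0.392 (adjusted p = 0.0490). The largest falls were those of tlr1 (-2.57), hist1h2a3 (-2.02), myhc4 (-1.63), cox7b (-1.15), irak1 (-0.98), fam168a (-0.97), hbae3 (-0.94) and adpgk2 (-0.91). Myhc4, a fast muscle myosin heavy chain, was at 1.38 ± 0.0129 against 0.377 ± 0.0514 (adjusted p = 0.0114), while the skeletal muscle list as a whole was not called. Cox7b, a subunit of cytochrome c oxidase, was at 14.6 ± 0.377 against 6.53 ± 0.212 (adjusted p = 0.0110), and irak1, a kinase of Toll-like receptor signalling, at 8.36 ± 0.291 against 4.20 ± 0.0869 (adjusted p = 0.0202). Without 1 library, the calls in this set ranged from 11 (without mutant replicate 2) to 21 (without wild-type replicate 2), with 18 without wild-type replicate 1 and 14 without mutant replicate 1.

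Of the 7 called lists, 4 had at least 5 members among the genes without repeated values, which is the minimum for a test. There, photoreceptor markers were higher in 16 of 17 members (median 0.47, camera adjusted p = 1.15e-05), cartilage markers had a median of -0.21 over 15 members (adjusted p = 0.00671), and aminoacyl-tRNA synthetases one of -0.24 over 15 members (adjusted p = 0.00761). The mTOR pathway was not called there (7 members, median -0.094, adjusted p = 0.876). With an estimated correlation none of the 22 lists tested in this set was called, with an adjusted p = 0.604 for photoreceptors, cartilage and synthetases alike. The exocrine pancreas had 0 such members, sterol synthesis 2 and enterocytes 4, so these calls rest on ratios with repeated values.

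A further rule took genes with a mean ratio of at least 10 and the smallest p, none of which passed in the fit of all genes. Besides sars2, spata6l and hbae1.1, those higher in mutants were lrp2b (2.49 ± 0.548 against 34.2 ± 4.80, SD, n = 2), tmem54b, kcnk7, pip4k2cb and ftr11, with log2 folds of 3.74, 3.43, 2.07, 3.64 and 1.75. Besides hist1h2a3 and tlr1, those lower were ms4a17a.1 (-3.92), ifit9 (-3.13), mhc2b (-2.47), osmr (-1.50), jac6 (-1.12) and trim35-31 (-1.12). Values were repeated in 3 libraries for lrp2b and in 4 for tmem54b, kcnk7, pip4k2cb, ms4a17a.1, ifit9, mhc2b and osmr. These are ratios of small whole numbers, so a small SD does not show that they were well measured. Lrp2b and pip4k2cb, for example, had the same value of 37.558 in mutant replicate 1.

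Both libraries of a genotype appear to have been divided by a single mRNA measurement. Of the tested genes, 89.3% had a ratio between the 2 wild-type libraries that another gene shared to 10 significant digits, and 90.6% had one between the 2 mutant libraries, but at most 14.5% between libraries of different genotypes. The error of the mRNA measurement is then absent from the spread between replicates, and p-values that rest on that spread leave it out. This holds for the p-values of single genes and for those of fry. A correlation between genes estimated from that spread does not include the mRNA error either. Camera at the preset correlation compares a list's members with the other genes, so mRNA error that differs from gene to gene enters its p-values. An mRNA error shared by the members of a list would move them together. Beyond the preset correlation, the p-values of the list calls do not allow for such a shared error.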

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

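The set of genes without repeated values, with its own alternatives, and the robust fit were chosen after the data were seen; the other alternatives were fixed before the data were examined. The count of 0 genes past the threshold in the fit of all genes stayed 0 after quantile normalization, median centring, without the trend, with the robust fit, with pseudocount 0.01, with the 2-fold minimum, and in all 4 fits that left out 1 library. It was 177 (82 higher, 95 lower) with no filter, where genes at 0 in both libraries of a genotype have no spread, 123 of 457 (78 and 45) with a minimum of 5 in 2 libraries, 6 (4 and 2) with pseudocount 1, and 36 of 2626 (19 and 17) without repeated values; the cause of these differences was not tested. The 36 calls became 22 (10 higher) without the trend and 24 (12 higher) with the robust fit, all among the 36. They became 28 after quantile normalization (23 among the 36) and 40 after median centring (36 among them). With pseudocount 0.01 they were 38 (36 among them) and with pseudocount 1 they were 40 (35 among the 36). Leaving out 1 library gave 11 to 21 calls (7 to 13 higher, 4 to 9 lower), of which 11 to 18 were among the 36; a group then holds 1 library, assumed to vary like the other group. Deviations of equally numbered libraries correlated at 0.0097 across all tested genes. Many of these are ratios of few reads, whose noise could hide a pairing, so a pairing of the replicates is not excluded. The replicate block gave 0 genes, 20 (11 higher, 9 lower) of the genes without repeated values and 6 lists, without the aminoacyl-tRNA synthetases (adjusted p = 0.0566). Of the 7 list calls, 0 (0 higher, 0 lower) held with an estimated correlation, although sterol synthesis (p = 0.0420) and photoreceptors (p = 0.0437) were below 0.05 unadjusted; fry called 5 of the 33 lists (1 lower), of which 2, enterocytes and photoreceptors, were among the 7, and gave the other 5 of the 7 adjusted p of 0.0765 to 0.208. In the set without repeated values 3 of 22 lists (1 higher) were called, and 0 (0 higher, 0 lower) with an estimated correlation. Leaving out 1 library gave 3 to 6 list calls (0 to 2 lower), and no filter ended the mTOR call (adjusted p = 0.0576). The exocrine pancreas, enterocyte and sterol synthesis calls held in all 4 of these fits. Each fit left out a Ribo-seq library and appears to have kept the same mRNA measurement of each genotype. Leaving out a library therefore does not test the error of the mRNA measurement. Among the named genes followed, directions turned for mycn (-0.17 without wild-type replicate 2, -0.084 without mutant replicate 1, at most 0.27 without the others) and myca (-1.29 to 0.13, positive without mutant replicate 2), neither called. Camera ranked ribosome biogenesis factors higher in the set without repeated values, although their median was -0.022, and sars2, the highest value in every library, has a log2 fold of 0 after quantile normalization by construction. Counted over genes and settings, 361 values of named genes kept their direction and side of the threshold and 46 passed it newly; of the values of lists followed through the alternatives, 124 kept both, 29 lost a call and 2 gained one. Count-based fits, including other size factors and voom, could not be run on ratios, nor could the log ratio of both assays.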

Other observations

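The gene groups of the first paragraphs were picked after the data were seen, as were the tests of mRNA error and of the spread of globin folds; the other tests were written down before their results. The 13 proteins encoded by the mitochondrial genome, all of them respiratory chain or ATP synthase subunits, had lower translation efficiency in mutants in 13 of 13 cases, with log2 folds from -0.35 (mt-nd4l) to -0.11 (mt-nd2) and a median of -0.20. Camera gave an unadjusted p of 0.00516 for the group at the preset correlation and 0.0977 with an estimated correlation. All 13 stayed lower after quantile normalization (median -0.27), after median centring (-0.22) and when any 1 library was left out (-0.17 to -0.22). The ratios of a genotype appear to rest on a single mRNA measurement, and an error shared by these 13 mRNAs would move them together. Leaving out a Ribo-seq library does not test such an error, so the 13 are not independent observations. No member passed alone; mt-co1, for example, was at 0.864 in wild type and 0.781 in mutants. The nuclear-encoded oxidative phosphorylation genes had a median of -0.020, and the difference between both groups was not tested.

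Collagen chains were lower in 39 of 52 genes, with a median log2 fold of -0.14 (camera p = 0.0183, unadjusted; p = 0.117 with an estimated correlation). The p was 0.0903 without wild-type replicate 1 and 0.156 without mutant replicate 1. The 31 chains that are in neither the cartilage nor the fibrous connective tissue list had a median of -0.11, with 23 lower, and camera gave an unadjusted p of 0.209 for them. Histone genes recognised by RefSeq names were 9, of which 5 had a wild-type translation efficiency of 10 or more; the 4 members lower in mutants were all among these 5. The largest fall was that of zgc:113983, from 388 ± 15.8 (SD, n = 2) to 77.8 ± 5.02, a log2 fold of -2.32 (adjusted p = 0.00154 in the set without repeated values), and zgc:163040 had one of -0.56. Of the others, hist1h2a3 was at 1025 ± 72.9 (SD, n = 2) in wild type and 251.8 ± 4.51 in mutants, and hist2h3c at 125 ± 5.03 against 71.1 ± 3.65, whereas si:dkey-23a13.21 was at 411 ± 20.4 against 692 ± 21.5. As a group they had a median of 0.031 and went both ways, and this median ran from -0.36 without wild-type replicate 1 to 0.42 without wild-type replicate 2. Camera gave an unadjusted p of 0.0856 for the group, and of 0.379 with an estimated correlation. Another 175 genes were listed at 0 in both wild-type libraries and above 0 in both mutant libraries, and 316 the reverse.

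Photoreceptor markers were higher and cartilage markers lower in mutants, but neither call held with an estimated correlation (adjusted p = 0.615 for each) or without mutant replicate 2 (adjusted p = 0.0742 for each; medians 0.413 and -0.239), and that of cartilage was also lost without wild-type replicate 1 (adjusted p = 0.0574; median -0.237). Chance error in the mRNA measurements of poorly covered genes was examined next. Both lists were picked from 33 because they were called, so the limit was 2.5% divided by 33 (0.0758%). Among members without repeated values the photoreceptor median of 0.47 lay above 100% of 10000 random lists of such genes, beyond that limit. The cartilage median of -0.21 lay above 0.63%, which is not beyond it. The test left out members with repeated values, which are ratios of few reads, and its random lists were not matched on coverage. It therefore leaves such error open for both lists. Embryos used for Ribo-seq and RNA-seq could also have differed in stage or tissue makeup, which would move a tissue's genes by a common amount. The spread of folds over cartilage markers was smaller than in most random lists (SD 0.15, percentile 1.68), as a common shift would give. Lists not called with camera also had small spreads over all their members, such as large-subunit ribosomal proteins (SD 0.147) and skeletal muscle (SD 0.193). The random lists were not matched on coverage, so a small SD does not single out such a shift. For photoreceptors (SD 0.355, percentile 77.65) the test does not decide either. An effect of the genotype on translation in these tissues stays open for both, and was not tested apart from the makeup of the embryos, since there is 1 RNA-seq sample per genotype.

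Globin genes moved apart, from -4.27 (hbbe3) to 3.46 (hbbe1.1) on the log2 scale. A different share of erythroid cells in the embryos of both assays would move them together, but the SD of their folds was 2.33 over 9 genes, which argues against it as the whole cause: of 10000 random gene sets matched on repeated values, whose folds include the error of the mRNA measurement, only 2.5% had an SD above 0.923. Reads shared between near-identical copies could be assigned differently in both assays; among genes without repeated values other than globins, 11.9% of 42 with symbols of tandem copies passed an absolute log2 fold of 0.5, against 7.18% of 2382 others (odds ratio 1.75, Fisher's exact p = 0.226), which leaves it open. Sequence variants of the globin cluster between the mutant line and the wild-type strain were not tested, nor was an effect of the genotype on translation.

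A translation efficiency of 10 or more was found for 235 tested genes, up to 16701 for sars2 in a mutant library. Footprint-sized fragments of small or ribosomal RNA genes lying inside a gene could inflate its ratio. Genes with such an RNA were 3 of 119 against 119 of 15411 others (odds ratio 3.32, Fisher's exact p = 0.0673), but only 50.6% of the 235 had a match in RefSeq, so the test is void. Whether mRNA without a poly(A) tail, as histone mRNA is, was lost from the RNA-seq samples could not be examined in ratios, and no biological explanation was tested.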
